A study of Mus musculus with 6 samples.

How the data were processed

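Cancer stem cells of mouse skin squamous cell carcinomas were profiled on Affymetrix MTA 1.0 arrays, 3 from WT and 3 from Sfrp1_KO mice. Genotype and replicate number were taken from the sample labels. The labels do not say that the samples of a genotype came from separate animals, so p-values measure the spread between these samples, which may be technical in part. The deposited table holds log2 probe set signals that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes; versions, level of summarisation and annotation build are not given in the sources used here. The scanner files and detection flags were not used here. The deposited log2 values reach 19.93, where a scanner of 16 bits ends at 16 log2 units, so a step that no label names stretched or shifted the scale. A difference of 1 log2 unit therefore need not be a doubling of RNA. No 2 arrays held identical values.

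The table has 72688 features, 6732 of them controls, and 65956 transcript clusters. The platform annotation gave 1 gene symbol to 30604 clusters and several to 2146, and listed none for 33206; only features with 1 symbol were named. Symbols were brought up to date through gene identifiers in a RefSeq table of assembly GRCm38.p6, where 22818 features matched and 827 symbols changed. That table was used only for names, chromosomes and neighbourhood, since the build behind the deposited annotation is not given in the sources used here, and no coordinates are printed. Of 355 genes with more than 1 feature the one with the highest mean over the 6 arrays was used, which left 30142 genes with no filter on dim ones. Near-identical paralogs (keratins, small proline-rich proteins, stefins, histones, MHC genes) and overlapping genes can share probe signal, and their values are uncertain to that extent.

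Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all 30142 genes, called at adjusted p under 0.05). A difference is Sfrp1_KO minus WT in deposited log2 units, with the moderated standard error (SE) and, for some genes, its 95% interval. Single genes of the sort and Sfrp1 also had an exact permutation test of the difference in means, whose smallest p with 3 arrays against 3 is 0.1. The background level of an array is its highest of 23 antigenomic background probe sets. Where all arrays of a genotype lay at or under it, a difference is written as "at least", the mean of the other genotype minus the mean over arrays of the background level; the adjusted p is that of the unbounded difference.

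Before the data were examined, 56 gene lists were written down, for Wnt and other pathways, keratinocyte states, cell cycle, stress and metabolism, 11 of them for markers of other cell types and 1 for sex-linked genes. Of 1370 entries 1160 were measured, and 89 genes stand in more than 1 list. Lists with at least 5 measured genes, 55 of them, were tested against all other genes with camera (inter-gene correlation preset at 0.01, adjusted over lists). The list of sex-linked genes had 4 measured members and was not tested. Camera with a correlation estimated per list, camera on ranks and the rotation test fry were run beside it. Counts of called members are given over all genes tested and adjusted over the list alone. Chromosomes were tested in the same way, and the neighbourhood of Sfrp1 was compared with the rest of its chromosome.

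The genes named were fixed by a rule: the Sfrp family, the sort markers, up to 12 genes per direction with the largest difference among called genes whose arrays separate (without predicted, pseudogene, microRNA, small nucleolar RNA and odorant or vomeronasal receptor names), and up to 4 members per list, called ones by size and otherwise those with the smallest p. The collagens of the fibroblast list and members of lists added later are named outside it and were chosen after their values were seen. Alternatives fixed beforehand were the replicate number as a block, dim features left out, the mean of all features of a gene, quantile normalization once more, array weights, eBayes with trend and robust options, each array left out in turn, a test without moderation, thresholds of 1 log2 unit, all features, and the other list tests.

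The procedure was tested on simulated data for this comparison, with 30142 genes. It recovered 29 of 50 genes changed by 1 log2 unit, 39 of 50 changed by 2, 48 of 50 changed by 3 and 47 of 50 changed by 4, with 7 false calls among 170. The changed genes were drawn from those above the median level, so recovery of dimmer genes was not tested. Camera recovered 4 of 4 lists shifted by 0.5, with 0 of 36 unshifted lists called, under the preset and the estimated correlation. The simulated genes were independent of each other, which genes on real arrays are not, so the simulation does not give the rate of false list calls here.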

Results

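Gene expression was measured in cancer stem cells sorted from skin squamous cell carcinomas of wild-type (WT) mice and of mice without Sfrp1 (Sfrp1_KO), the gene of a secreted antagonist of Wnt signalling. The tumours had been raised with DMBA, a mutagen given on 3 days, and then with the tumour promoter TPA, given 2 times a week for 30 to 40 weeks. Cells negative for lineage markers and positive for Epcam, α6 integrin (encoded by Itga6) and CD34 were sorted, and RNA from 3 WT and 3 Sfrp1_KO samples was hybridised to 1 whole-transcript Affymetrix MTA 1.0 array each. The comparison of the genotypes asks how the stem cell fraction of these carcinomas differs in expression when Sfrp1 is absent. The array medians lay between 4.32 and 4.46 log2 units, and the highest of 23 background probe sets lay between 4.82 and 5.10 on each array. Between 33.2% and 42.5% of the 30142 genes compared stood above that background level. The number of arrays limits the precision of every value. The largest value was 19.93, above the 16 bits of a scanner, so the scale was stretched or shifted by a step not given in the sources used here. Differences are therefore given in deposited log2 units and not as folds.

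Sfrp1, the targeted gene, stood at 5.75 ± 0.30 (SD, n = 3) in WT and at 5.12 ± 0.03 (SD, n = 3) in Sfrp1_KO. Each Sfrp1_KO array lay below each WT array, and the knockout mean was close to the highest background probe set of those arrays, at up to 5.10. The difference was -0.64 (SE 0.15, 95% CI -1.0 to -0.27). It did not pass the limma test over all genes (adjusted p = 0.0969), and the two-sided exact permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. The labels do not say which part of the gene is deleted, so a probe set outside that part would not check the genotype. Of the other secreted Frizzled-related proteins, Sfrp2 (4.15 ± 0.07 in WT, 4.11 ± 0.10 in Sfrp1_KO; SD, n = 3), Frzb (3.91 ± 0.12 and 3.92 ± 0.06) and Sfrp4 (4.27 ± 0.29 and 4.29 ± 0.10) were under the background level in both genotypes, and Sfrp5 was at 5.48 ± 0.10 and 5.44 ± 0.26. None of the 5 family members passed the limma test over all genes. Sfrp1 passed when adjusted over the list alone (limma adjusted p = 0.0251), and the list did not shift (median -0.04, camera adjusted p = 0.540).

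Among the markers of the sort, Epcam, the epithelial cell adhesion molecule, fell from 7.59 ± 1.03 to 5.03 ± 0.17 (SD, n = 3), a level around background, and Itga6 fell from 9.51 ± 0.64 to 7.62 ± 0.18. The differences were -2.56 (SE 0.48, adjusted p = 0.0455) and -1.89 (SE 0.31, adjusted p = 0.0292). Cd34, the third positive marker, was at 9.42 ± 0.15 in WT and 10.99 ± 0.71 in Sfrp1_KO and did not pass (difference 1.57, SE 0.34, adjusted p = 0.0714). On the lineage side, Ptprc, which encodes the leukocyte antigen CD45, lay under background in both genotypes (4.18 ± 0.13 and 4.23 ± 0.11), and the endothelial marker Pecam1 was at 5.08 ± 0.33 and 4.70 ± 0.10 (adjusted p = 0.385). Exact permutation p-values were 0.1 for Epcam, Itga6, Cd34 and Pecam1, the smallest possible, and 0.7 for Ptprc. Epcam was not called without WT replicate 1 or any 1 of the Sfrp1_KO arrays (adjusted p up to 0.184), nor Itga6 without WT replicate 2 or any 1 of the Sfrp1_KO arrays (up to 0.111), while Cd34 passed without Sfrp1_KO replicate 3 (1.97, adjusted p = 0.00664), after quantile normalization once more (1.53, limma adjusted p = 0.0314) and with array weights (1.70, limma adjusted p = 0.0299). Epcam and Itga6 were also not called with the replicate number as a block (adjusted p = 0.0981 and 0.0608).

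**Figure D1:**
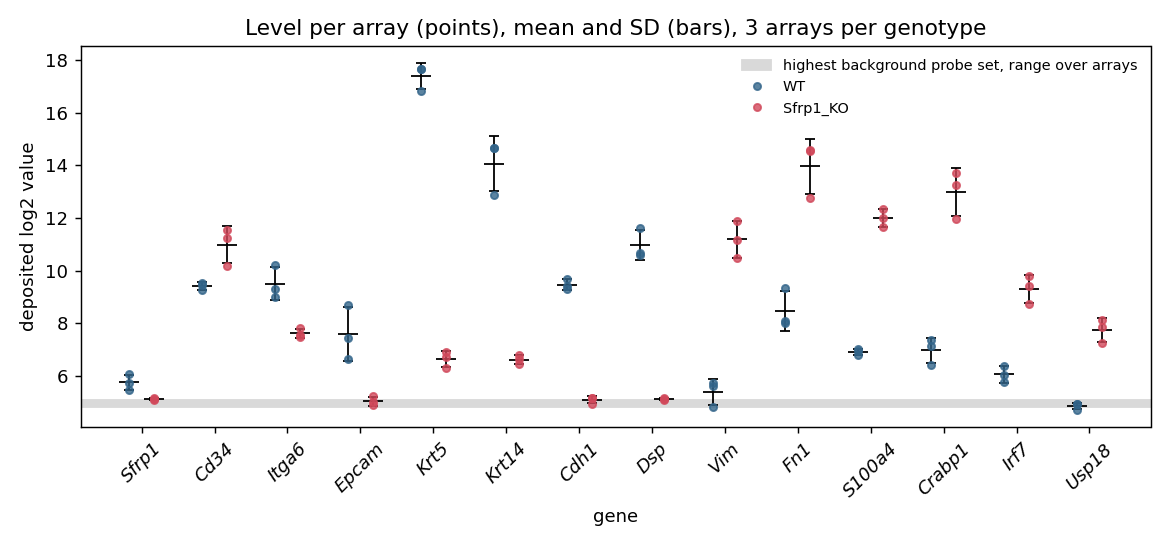
Deposited log2 level (y axis) of Sfrp1, 3 markers of the sort and 10 further genes (x axis) on each of 3 WT and 3 Sfrp1_KO arrays; points are arrays, bars the mean and SD, and the grey band spans the highest background probe set of each array (4.82 to 5.10). Krt5 stood at 17.39 in WT and 6.64 in Sfrp1_KO, and Vim at 5.38 and 11.19.

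In total 552 genes rose and 437 fell in Sfrp1_KO, with adjusted p under 0.05 by limma, and 18 and 24 of these differed by at least 4 log2 units. All 989 called genes separated the arrays of the genotypes. Over all genes 5992 (19.9%) did so, where chance gives 10% for a single gene. Calls select for such separation and genes vary together, so neither share is a test of the genotype difference. The knockout arrays resembled each other most, with Pearson correlations across genes of 0.985 to 0.991, against 0.975 to 0.978 among WT arrays and 0.949 to 0.958 between genotypes; genes are not independent replicates. The first principal component held 55.7% of the variance and separated the genotypes. The counts depended on the arrays used: they were 223 higher and 125 lower without Sfrp1_KO replicate 1, 191 and 100 without replicate 2, 487 and 190 without replicate 3, 346 and 407 without WT replicate 1, 299 and 358 without WT replicate 2 and 261 and 315 without WT replicate 3. A test without moderation of the variances called 14 and 21, and a minimum difference of 1 log2 unit left 295 and 244.

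Among the 12 largest falls, Krt5 and Krt14, the keratin pair of basal epidermal cells, fell from 17.39 ± 0.50 to 6.64 ± 0.30 (SD, n = 3) and from 14.07 ± 1.04 to 6.62 ± 0.16. The log2 differences were -10.74 (SE 0.27) and -7.45 (SE 0.48). Krt16 and Krt17, keratins of injured and hyperproliferative epidermis, fell by at least 7.96 and at least 4.97, to background. Aqp3, a water and glycerol channel of the epidermis, fell by 8.44 (SE 0.39). The desmosomal genes Dsp (-5.84, SE 0.27) and Dsg3 (-5.80, SE 0.53) fell as well. The remaining genes among the 12 largest falls were Slitrk6, a neuronal transmembrane protein (at least 5.89), the glutathione transferase gene Gsta4 (-6.30, SE 1.04), the cornified envelope gene Sprr2b (at least 4.83), Serpinb5, which encodes maspin (-5.67, SE 0.26), and Ly6d (at least 4.56). Adjusted p-values of these 12 ran from 0.000127 for Krt5 to 0.0478 for Sprr2b. Krt16, Slitrk6, Gsta4, Sprr2b and Ly6d were not called without Sfrp1_KO replicate 2 (adjusted p = 0.0816, 0.0601, 0.133, 0.182 and 0.0530). Calls also ended without WT replicate 2 (Gsta4 and Sprr2b), Sfrp1_KO replicate 1 (Krt16, Slitrk6, Gsta4 and Sprr2b) and Sfrp1_KO replicate 3 (Krt16, Gsta4 and Sprr2b). The block by replicate number ended the calls of Gsta4 and Sprr2b as well (adjusted p = 0.0543 and 0.0895). The other 7 of the 12 kept their calls without any 1 array. Sprr2b belongs to a family of near-identical genes, whose probes can share signal.

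Of 18 basal keratinocyte genes 11 fell and none rose, among them Itga3 (-3.69, SE 0.67) and the P-cadherin gene Cdh3 (-3.34, SE 0.23) besides the keratins. Adjusted over the list alone 14 fell and 1 rose. The median was -1.90 (camera adjusted p = 5.72e-15; adjusted p = 0.284 with an estimated correlation). Of 29 genes of the epithelial side of the epithelial-mesenchymal transition 12 fell, including the E-cadherin gene Cdh1 (9.47 ± 0.20 to 5.09 ± 0.14, -4.38, SE 0.13, adjusted p = 0.000167) and Pkp1, a desmosomal plaque protein (at least 3.78). With adjustment over the list alone 19 fell and 1 rose, and the median was -0.98 (camera adjusted p = 2.26e-16; adjusted p = 0.138 with an estimated correlation). Of 34 suprabasal differentiation genes 7 fell, such as Calml3 (at least 2.61), Dmkn (-2.73, SE 0.46), Dsg1a (at least 1.86) and Dsg1b (-2.17, SE 0.41), and 20 fell when adjusted over the list alone. Their median was -1.04 (camera adjusted p = 1.53e-13; adjusted p = 0.377 with an estimated correlation). Of 13 wound keratins and alarmins 5 fell, Stfa1 (at least 4.31) and Il1f9 (at least 3.03) among them, and 8 when adjusted over the list alone. The wound list had a median of -2.60 (camera adjusted p = 6.14e-07; adjusted p = 0.229 with an estimated correlation), and of -1.44 without WT replicate 1. None of 25 hair follicle genes passed in either adjustment (over all genes or adjusted over the list alone), while their median was -0.09 (camera adjusted p = 0.0173; adjusted p = 0.681 with an estimated correlation); Krt79 was at 6.55 ± 0.50 and 5.49 ± 0.19 (adjusted p = 0.0949). Of 15 sebaceous gland genes Fasn, the fatty acid synthase, fell (-1.16, SE 0.17), 2 fell when adjusted over the list alone, and the list did not shift (median -0.06, adjusted p = 0.437). Itga3, Calml3, Dmkn, Dsg1a, Dsg1b, Stfa1 and Il1f9 were not called without Sfrp1_KO replicate 2 (adjusted p = 0.161, 0.102, 0.137, 0.101, 0.185, 0.0848 and 0.155), nor was Fasn without Sfrp1_KO replicate 1 (adjusted p = 0.0868). Further calls ended without WT replicate 1 (Calml3 and Fasn), WT replicate 2 (all but Calml3 and Dsg1a), Sfrp1_KO replicate 1 (all of these genes) and Sfrp1_KO replicate 3 (all but Fasn). The hair follicle list lost its call without Sfrp1_KO replicate 1 or 2 (adjusted p up to 0.0641), and its median was -0.049 without Sfrp1_KO replicate 2, -0.20 without Sfrp1_KO replicate 3, -0.17 with dim features left out and -0.14 with array weights. Dsg1b (0.0617) and Il1f9 (0.0519) were not called after quantile normalization once more. Itga3, Calml3, Dmkn, Dsg1b and Il1f9 were also not called with the replicate number as a block (adjusted p = 0.0577, 0.0503, 0.0552, 0.0641 and 0.0780). Of genes not called, the hair follicle gene Lhx2 passed without WT replicate 1 (-0.77, adjusted p = 0.0297) and Padi3, which citrullinates proteins of the hair follicle, without WT replicate 3 (-2.52, adjusted p = 0.0406).

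The largest rises were those of the water channel gene Aqp1 (6.12, SE 0.38) and the retinoic acid binding protein gene Crabp1 (6.02, SE 0.47). Vim, the intermediate filament of mesenchymal cells, rose by 5.80 (SE 0.40) from 5.38 ± 0.50 to 11.19 ± 0.70 (SD, n = 3). Mgp, an inhibitor of calcification, rose by 5.69 (SE 0.23), the fibronectin gene Fn1 by 5.49 (SE 0.59) and the calcium-binding protein gene S100a4 by 5.09 (SE 0.18). Also among the 12 largest rises were the apolipoprotein gene Apod (5.13, SE 0.48), Ace, the angiotensin-converting enzyme (5.06, SE 0.44), the metalloproteinase inhibitor gene Timp3 (at least 4.22), the Wnt antagonist gene Dkk2 (at least 3.78), the semaphorin gene Sema7a (4.28, SE 0.35) and the basement membrane gene Nid1 (4.11, SE 0.44). Their adjusted p-values ran from 0.000212 for S100a4 to 0.00841 for Fn1, and all 12 passed without any 1 array.

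Of 27 genes of the mesenchymal side of the transition 8 rose and Tnc, which encodes tenascin C, fell by at least 3.09; adjusted over the list alone 13 rose and 4 fell. The median was 0.34 (camera adjusted p = 1.53e-05; adjusted p = 0.386 with an estimated correlation), and 0.19 without Sfrp1_KO replicate 1. Fibroblast markers were divided: of 19, the PDGF receptor gene Pdgfrb rose by 3.72 (SE 0.38) and Thy1 by 0.89 (SE 0.14), while Fbln1 fell by at least 0.78. Of the markers 5 rose and 3 fell when adjusted over the list alone. The collagen genes that fibroblasts express most did not pass: Col1a1 was at 6.77 ± 0.75 and 6.32 ± 0.42 (SD, n = 3), Col1a2 at 5.59 ± 0.44 and 6.34 ± 0.54, and Col3a1 at 5.87 ± 0.36 and 6.82 ± 0.29. The fibroblast list did not shift (median 0.02, adjusted p = 0.202), but did without WT replicate 3 (median 0.24, adjusted p = 0.00787). Of 25 matrix metalloproteinases and inhibitors 4 rose, Timp2 by 2.97 (SE 0.16), Mmp2 by 1.92 (SE 0.29), Mmp11 by at least 0.36 and Timp3 as above. With adjustment over the list alone 4 rose and 1 fell, and the list median was -0.03 while its mean of 0.23 and its test pointed up (adjusted p = 0.354). Among 28 basement membrane and integrin genes 4 rose, led by Nid1, and 4 fell, among them Itga3, Lama3 (-1.91, SE 0.36) and Itga6. In this list 8 rose and 6 fell when adjusted over the list alone, and the list did not shift (median 0.05, mean -0.02, camera pointing up with adjusted p = 0.202). Tnc, Mmp2, Lama3 and Itga3 were not called without Sfrp1_KO replicate 2 (adjusted p = 0.0684, 0.104, 0.188 and 0.161), nor were Thy1 and Mmp11 without Sfrp1_KO replicate 1 (adjusted p = 0.10 and 0.0884). Other single arrays that ended calls were WT replicate 1 (all but Tnc, Lama3 and Itga3), WT replicate 2 (all but Tnc), WT replicate 3 (Thy1 and Mmp11), Sfrp1_KO replicate 1 (all of these genes), Sfrp1_KO replicate 2 (all of these genes) and Sfrp1_KO replicate 3 (Lama3 and Itga3). The block by replicate number ended the calls of Mmp2, Mmp11, Lama3 and Thy1 as well (adjusted p = 0.0886, 0.0971, 0.0900 and 0.0766).

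Of 31 interferon-response genes 21 rose, none fell and 10 did not pass, and 26 rose when adjusted over the list alone. The list median was 0.91 (camera adjusted p = 3.78e-30; adjusted p = 0.229 with an estimated correlation). Bst2, which encodes tetherin, rose by 3.92 (SE 0.60), the transcription factor gene Irf7 by 3.25 (SE 0.30), the ISG15 protease gene Usp18 by 2.88 (SE 0.23) and Rtp4 by 2.32 (SE 0.27). Of 16 antigen presentation genes B2m, the light chain of MHC class I, rose from 13.96 ± 0.47 to 17.24 ± 0.77 (SD, n = 3; 3.28, SE 0.42). Adjusted over the list alone 5 of them rose (median 0.19, or 0.30 with dim features left out; camera adjusted p = 0.00319; adjusted p = 0.586 with an estimated correlation). Leukocyte and macrophage markers were also higher as a list in the same arrays, though none of 19 passed over all genes: Lyz2 was at 4.94 ± 0.22 and 6.91 ± 1.00 and C1qb at 4.11 ± 0.10 and 5.42 ± 0.73. With adjustment over the list alone 10 of them rose (median 0.32, camera adjusted p = 6.14e-07; adjusted p = 0.490 with an estimated correlation). Without Sfrp1_KO replicate 3 Lyz2, Laptm5, C1qb and C1qa passed over all genes (adjusted p = 0.0352, 0.0257, 0.00436 and 0.0264), and Laptm5 and C1qa also with array weights (0.0475 and 0.0489). Of 31 cytokines and chemokines Il34, a ligand of the CSF1 receptor, rose by 3.52 (SE 0.12) and Cxcl10 by at least 0.32. Among these genes 3 rose and 5 fell when adjusted over the list alone, and the list did not shift (median -0.10, mean -0.05, camera pointing up with adjusted p = 0.661). None of 17 NF-kB feedback genes passed in either adjustment (median 0.04, adjusted p = 0.553), and Nfkbie did with array weights (0.0490). Bst2, Rtp4, B2m and Cxcl10 were not called without Sfrp1_KO replicate 2 (adjusted p = 0.112, 0.0653, 0.0751 and 0.112). Calls also ended without WT replicate 2 (Bst2), WT replicate 3 (Bst2 and Cxcl10), Sfrp1_KO replicate 1 (all of these genes) and Sfrp1_KO replicate 3 (Cxcl10). B2m and Cxcl10 were also not called with the replicate number as a block (adjusted p = 0.0642 and 0.0796).

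Called genes of the Wnt pathway went in both directions. The receptor list shifted lower and the antagonist list higher by camera with the preset correlation and by fry (fry adjusted p = 0.00926 and 0.0481). Neither did with an estimated correlation, and the target and ligand lists shifted by none of these tests. Of 34 Wnt/beta-catenin target genes, Tbx3 rose by 1.01 (SE 0.10) and Twist1 by at least 0.22, and Cd44, a hyaluronan receptor, fell by 3.44 (SE 0.49) and Cldn1 by at least 0.29. Of the targets 3 rose and 4 fell when adjusted over the list alone, and the list did not shift (median -0.01, adjusted p = 0.767). None of 23 Wnt ligands and R-spondins passed in either adjustment (median -0.02, adjusted p = 0.767). The median level of the ligand list was 4.17 in both genotypes, under the lowest background level of 4.82. That of the target list was 4.93 in WT and 4.91 in Sfrp1_KO, within the range of the background levels. Medians near 0 there do not show that ligands or targets were unchanged. Of 16 Frizzled receptors and co-receptors Ptk7 (-1.33, SE 0.15), Lrp5 (-1.11, SE 0.10) and Fzd6 (-1.02, SE 0.10) fell. Adjusted over the list alone 4 fell and 3 rose (median -0.13, camera adjusted p = 0.0305; adjusted p = 0.377 with an estimated correlation). Among 12 secreted Wnt antagonists outside the Sfrp family, Dkk2 rose as above and Igfbp4 rose by 2.92 (SE 0.35), while Sostdc1 fell by 1.74 (SE 0.26), and the counts were unchanged at 2 and 1 when adjusted over the list alone (median 0.09, camera adjusted p = 0.0264; adjusted p = 0.377 with an estimated correlation). Cd44, Ptk7, Igfbp4 and Sostdc1 were not called without Sfrp1_KO replicate 2 (adjusted p = 0.0749, 0.0541, 0.0653 and 0.106), nor was Twist1 without Sfrp1_KO replicate 1 (adjusted p = 0.0907), nor was Cldn1 without WT replicate 3 (adjusted p = 0.0737). Further calls ended without WT replicate 1 (Twist1), WT replicate 2 (Twist1 and Cldn1), WT replicate 3 (Cldn1 and Sostdc1), Sfrp1_KO replicate 1 (all but Ptk7 and Igfbp4), Sfrp1_KO replicate 2 (all of these genes) and Sfrp1_KO replicate 3 (all but Twist1, Ptk7 and Igfbp4). The receptor list was not shifted without WT replicate 1 or Sfrp1_KO replicate 3 (adjusted p up to 0.150), nor the antagonist list without WT replicate 1 or 2 or Sfrp1_KO replicate 2 (up to 0.106). The receptor list also lost its call with dim features left out (0.0794), after quantile normalization once more (0.103), with array weights (0.107) and on ranks (0.0782), and the antagonist list with dim features left out (0.0727) and with array weights (0.0560). With dim features left out the medians of the 2 lists were -0.23 and 0.39. The antagonist median was 0.051, 0.16 and 0.14 without WT replicate 1, WT replicate 3 and Sfrp1_KO replicate 2. The block by replicate number ended the calls of Twist1 and Sostdc1 as well (adjusted p = 0.0832 and 0.0813).

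Of 28 skin and cancer stem cell markers, Sox2, a transcription factor of skin tumour stem cells, rose by 2.04 (SE 0.34), and 5 fell, among them Cd44, Epcam and Itga6. Here 6 rose and 5 fell when adjusted over the list alone, and the list did not shift (median -0.04, adjusted p = 0.882). Sox2 was also the 1 of 15 pluripotency factors that passed in either adjustment (median -0.02, mean 0.14, adjusted p = 0.437). In the Notch pathway Rbpj, the DNA-binding partner of Notch, rose by 1.54 (SE 0.15) and Dtx4 by 0.42 (SE 0.08), while Notch1 (-1.23, SE 0.23) and its ligand gene Jag2 (-0.88, SE 0.13) fell. These were 2 and 2 of 25 genes, also when adjusted over the list alone, and the list did not shift (median -0.01, adjusted p = 0.613). In the TGF-beta and BMP pathway 6 of 31 genes rose, including Tgfbr3 (2.65, SE 0.20), Bmp2 (2.05, SE 0.21) and the BMP antagonist gene Grem1 (1.55, SE 0.28), and 2 fell, including the activin antagonist gene Fst (-1.62, SE 0.10). When adjusted over the list alone, the counts were 7 and 3 (median 0.07, camera adjusted p = 0.0264; adjusted p = 0.490 with an estimated correlation). Of 23 Hippo/YAP target genes 5 rose, such as Asap1 (2.65, SE 0.18), the receptor kinase gene Axl (2.48, SE 0.37) and Tead1 (1.21, SE 0.23), and Nuak2 fell by at least 1.09. The Hippo counts were 6 and 4 when adjusted over the list alone, with no shift (median 0.03, adjusted p = 0.365). Among 24 MAPK feedback and Ras output genes the feedback inhibitor genes Spry4 and Spry1 rose by 1.90 (SE 0.22) and 0.61 (SE 0.08), Etv5 rose by 0.86 (SE 0.13) and Epha4 fell by at least 0.51. With adjustment over the list alone 8 rose and 3 fell (median 0.18, camera adjusted p = 0.00829; adjusted p = 0.679 with an estimated correlation). None of 18 Hedgehog pathway genes passed in either adjustment (median 0.04, adjusted p = 0.437), at median levels of 4.76 in WT and 4.84 in Sfrp1_KO, around background. With array weights Foxf1 (1.12, adjusted p = 0.0335) and Boc (-1.12, adjusted p = 0.0426) passed, as did Foxf1 without Sfrp1_KO replicate 3 (0.0277) and Boc without WT replicate 1 (0.0144). Sox2, Notch1, Jag2, Axl, Nuak2, Spry4, Spry1, Etv5, Epha4 and Cd44 were not called without Sfrp1_KO replicate 2 (adjusted p = 0.130, 0.161, 0.106, 0.108, 0.0836, 0.0623, 0.0628, 0.0913, 0.0853 and 0.0749), nor were Dtx4, Grem1 and Tead1 without Sfrp1_KO replicate 1 (adjusted p = 0.199, 0.142 and 0.150). Other single arrays that ended calls were WT replicate 1 (Sox2, Dtx4, Notch1, Jag2, Grem1, Axl, Tead1 and Etv5), WT replicate 2 (Sox2, Dtx4, Jag2, Grem1, Tead1 and Nuak2), WT replicate 3 (Dtx4, Notch1, Grem1, Axl, Tead1 and Etv5), Sfrp1_KO replicate 1 (all of these genes), Sfrp1_KO replicate 2 (all of these genes) and Sfrp1_KO replicate 3 (Sox2, Dtx4, Notch1, Jag2, Nuak2, Epha4 and Cd44). The TGF-beta list was not shifted without WT replicate 3 or Sfrp1_KO replicate 1 or 2 (adjusted p up to 0.279), nor the MAPK list without WT replicate 3 or Sfrp1_KO replicate 2 (up to 0.213). The TGF-beta median was 0.0095 without WT replicate 3, 0.035 without Sfrp1_KO replicate 1 and 0.14 with array weights, and the MAPK median 0.41 without WT replicate 1. On ranks neither list was shifted (0.126 and 0.0782), and with trend and robust options Dtx4 (0.0966) and Tead1 (0.0527) were not called. Sox2, Notch1, Jag2, Dtx4, Grem1, Nuak2 and Spry1 were also not called with the replicate number as a block (adjusted p = 0.0751, 0.0900, 0.0744, 0.139, 0.111, 0.0555 and 0.0611). The block also ended the call of the TGF-beta list (0.0528).

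Of 18 cholesterol biosynthesis genes 8 fell and none rose, among them Hmgcs1 (-1.06, SE 0.16), Nsdhl (-0.92, SE 0.16), Ebp (-0.82, SE 0.13) and Dhcr7 (-0.74, SE 0.11). Adjusted over the list alone 13 fell and 1 rose (median -0.50, camera adjusted p = 1.11e-09; adjusted p = 0.284 with an estimated correlation). Of 42 oxidative phosphorylation genes Ndufa4 fell by 3.68 (SE 0.40), also the 1 that fell when adjusted over the list alone, and the median was -0.28 (camera adjusted p = 6.14e-07; adjusted p = 0.681 with an estimated correlation). Of 5 mitochondrially encoded transcripts ND2 fell by 1.66 (SE 0.24), again the 1 that fell when adjusted over the list alone (median -0.61, camera adjusted p = 0.0239; adjusted p = 0.490 with an estimated correlation). In glycolysis Ldha, the lactate dehydrogenase, fell by 1.43 (SE 0.16), 1 of 20 in either adjustment (median -0.17, adjusted p = 0.198). Of 25 hypoxia response genes P4ha1 rose by 0.85 (SE 0.13) and Car12 (-1.95, SE 0.23) and Ldha fell. In the same list 2 rose and 4 fell when adjusted over the list alone (median -0.08, adjusted p = 0.198). Without WT replicate 3 both lists shifted lower, with medians of -0.24 (adjusted p = 0.00741) and -0.65 (adjusted p = 1.93e-05). Castor1 fell by 1.92 (SE 0.29), 1 of 24 mTORC1-linked genes in either adjustment (median -0.10, adjusted p = 0.301), and Gsta4 was the 1 of 20 NRF2 target genes (median -0.13, adjusted p = 0.553, and 0.0370 without WT replicate 1). Of 24 ABC transporters Abca1, a cholesterol exporter, rose by 1.23 (SE 0.18) and Abcc3 fell by at least 0.97, and 1 rose and 3 fell when adjusted over the list alone (median -0.01, adjusted p = 0.553). Nsdhl, Ebp, Dhcr7, ND2, Ldha, P4ha1, Car12, Castor1, Abca1, Abcc3 and Gsta4 were not called without Sfrp1_KO replicate 2 (adjusted p = 0.147, 0.112, 0.0922, 0.0996, 0.0524, 0.108, 0.0616, 0.109, 0.0749, 0.121 and 0.133), nor was Hmgcs1 without Sfrp1_KO replicate 1 (adjusted p = 0.0761). Calls also ended without WT replicate 1 (Nsdhl and Ebp), WT replicate 2 (Hmgcs1, Nsdhl, Dhcr7, P4ha1, Abca1 and Gsta4), WT replicate 3 (Hmgcs1, Ebp, Dhcr7, Castor1, Abca1 and Abcc3), Sfrp1_KO replicate 1 (all but Ldha), Sfrp1_KO replicate 2 (all of these genes) and Sfrp1_KO replicate 3 (all but Dhcr7, Ldha and Car12). The mitochondrial list was not shifted without Sfrp1_KO replicate 1 (median -0.40, adjusted p = 0.0673) or with dim features left out (0.0668). The block by replicate number ended the calls of Hmgcs1, Nsdhl, Dhcr7, P4ha1, Abca1 and Abcc3 as well (adjusted p = 0.10, 0.0627, 0.0617, 0.0597, 0.0854 and 0.0550).

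None of 31 G2/M genes passed in either adjustment, and 28 of them were higher in Sfrp1_KO by a small amount, such as Top2a at 6.34 ± 0.15 and 7.09 ± 0.26 (SD, n = 3; adjusted p = 0.0578). Top2a passed with the replicate block (0.0468), with dim features left out (0.0475), after quantile normalization once more (0.0245) and with array weights (0.0437), and Kif20a, a mitotic kinesin gene, passed in the last 2 (0.0257 and 0.0469). The median of the G2/M list was 0.16 (camera adjusted p = 1.09e-06; adjusted p = 0.502 with an estimated correlation), and 0.29 and 0.31 without WT replicate 2 and Sfrp1_KO replicate 3. Of 30 G1/S and replication genes Ccne1, which encodes cyclin E1, fell by at least 0.69, 2 fell when adjusted over the list alone, and the list did not shift (median 0.02, adjusted p = 0.628). Of 24 immediate-early genes 3 rose, the AP-1 gene Fosb by 4.09 (SE 0.69), Nr4a2 by 1.10 (SE 0.16) and Klf2 by at least 0.17. With adjustment over the list alone 8 rose (median 0.40, or 0.70 with dim features left out; camera adjusted p = 9.52e-06; adjusted p = 0.490 with an estimated correlation). The heat shock genes Hsph1 and Dnajb4 rose by 1.00 (SE 0.17) and 0.58 (SE 0.09), while 7 of 15 rose and 2 fell when adjusted over the list alone (median 0.30, camera adjusted p = 0.0175; adjusted p = 0.681 with an estimated correlation). Hspa5, the chaperone BiP, and Ppp1r15a rose by 1.52 (SE 0.26) and 0.87 (SE 0.14), 2 of 23 genes of the unfolded protein response in either adjustment. This list did not shift (median 0.06, adjusted p = 0.0647) but did without WT replicate 1 (0.15, adjusted p = 0.000316) and without Sfrp1_KO replicate 3 (0.09, adjusted p = 0.00266). It also shifted after quantile normalization once more (0.08, adjusted p = 0.0493) and with array weights (0.13, adjusted p = 0.00276), and with the replicate block (adjusted p = 0.0399). Of 25 p53 target genes Perp, which is also a desmosome component, fell by 4.56 (SE 0.41), the 1 in either adjustment (median -0.22, camera adjusted p = 0.0200; adjusted p = 0.681 with an estimated correlation). None of 22 apoptosis regulators passed in either adjustment (median 0.18, camera adjusted p = 0.0113; adjusted p = 0.559 with an estimated correlation).

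Ezh1, a Polycomb methyltransferase gene, rose by 1.53 (SE 0.17) and Jarid2 fell by 0.98 (SE 0.17), 1 and 1 of 23 Polycomb and DNA methylation genes in either adjustment (median -0.03, mean 0.07, adjusted p = 0.437). None of 32 DNA repair genes, 32 cytoplasmic ribosomal protein genes and 11 replication-dependent histone genes passed in either adjustment (medians -0.03, -0.05 and 0.08, adjusted p = 0.781, 0.508 and 0.230). Without WT replicate 2 the ribosomal list shifted lower (median -0.14, adjusted p = 0.0247) and the histone list higher (0.28, adjusted p = 0.000482). Ccne1, Fosb, Klf2, Hsph1, Dnajb4 and Jarid2 were not called without Sfrp1_KO replicate 2 (adjusted p = 0.128, 0.141, 0.186, 0.156, 0.106 and 0.166), nor were Hspa5 and Ppp1r15a without Sfrp1_KO replicate 1 (adjusted p = 0.132 and 0.124), nor was Nr4a2 without WT replicate 3 (adjusted p = 0.0742). Further calls ended without WT replicate 1 (Klf2, Dnajb4 and Jarid2), WT replicate 2 (all but Fosb and Jarid2), WT replicate 3 (all but Dnajb4), Sfrp1_KO replicate 1 (all but Klf2), Sfrp1_KO replicate 2 (all but Nr4a2) and Sfrp1_KO replicate 3 (all but Nr4a2, Hspa5 and Ppp1r15a). Heat shock genes were not shifted as a list without WT replicate 2 or Sfrp1_KO replicate 2 (adjusted p up to 0.217), p53 targets without WT replicate 1 or Sfrp1_KO replicate 3 (up to 0.345), and apoptosis regulators without WT replicate 2 or 3 (up to 0.0624). The p53 list also lost its call with dim features left out (0.0767) and with array weights (0.167), and the heat shock list on ranks (0.161). The p53 median was -0.13 without WT replicate 1 and -0.15 with array weights, and the heat shock median 0.12 without WT replicate 2. Klf2 was not called with array weights (0.0972), Jarid2 after quantile normalization once more (0.0535), nor Hspa5 (0.0556) and Hsph1 (0.0645) with trend and robust options. Ccne1, Fosb, Nr4a2, Klf2, Hsph1, Dnajb4, Hspa5, Ppp1r15a and Jarid2 were also not called with the replicate number as a block (adjusted p = 0.108, 0.0904, 0.0724, 0.0857, 0.10, 0.0611, 0.0668, 0.0614 and 0.0617).

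**Figure D2:**
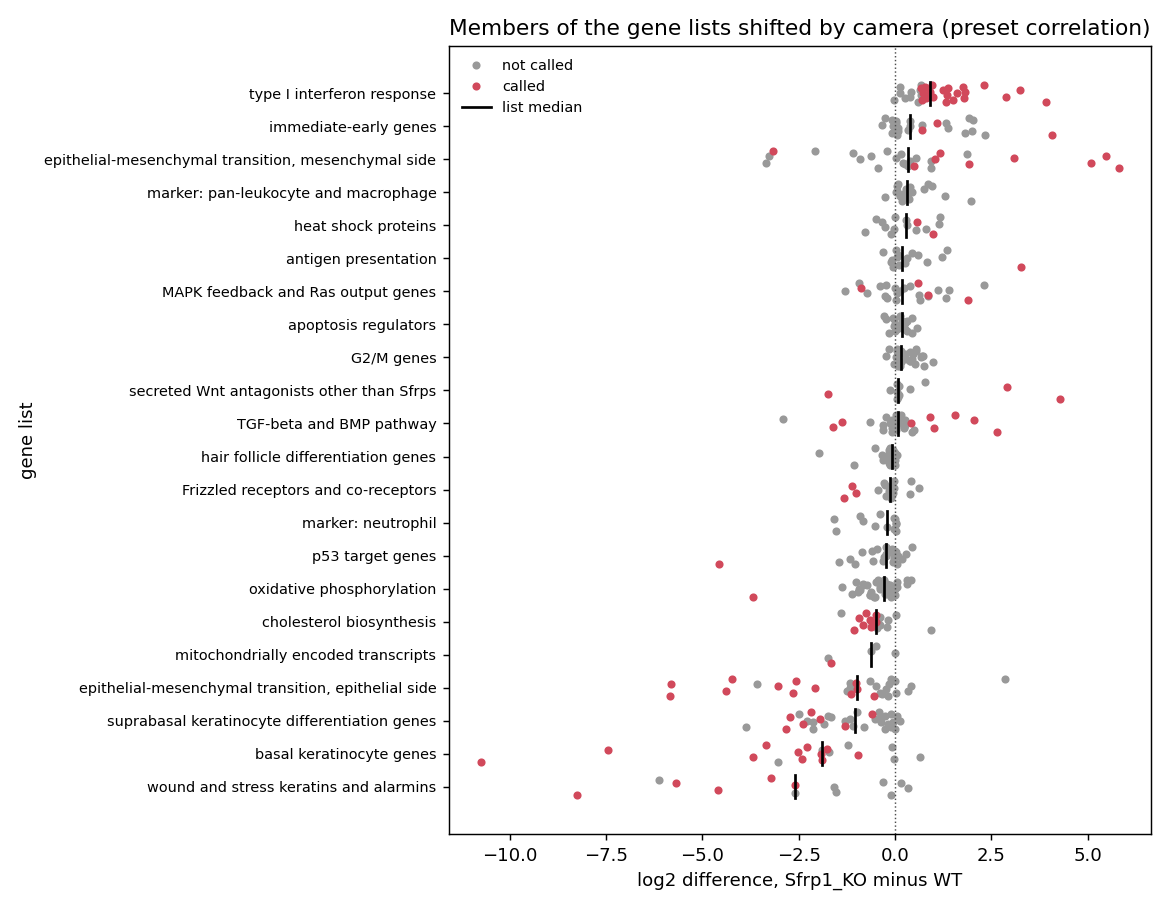
Log2 difference, Sfrp1_KO minus WT (x axis), of the measured members of the 22 gene lists (y axis) that camera called shifted with its preset correlation; red points are genes called over all genes, grey points are not called, and black bars are list medians. Medians ran from -2.60 for wound keratins and alarmins to 0.91 for interferon genes; none of these lists was called with an estimated correlation.

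In all, 11 of the 55 lists tested shifted higher and 11 lower by camera with a preset correlation of 0.01. With correlations estimated from these arrays none did (lowest adjusted p = 0.138), although 6 had an unadjusted p under 0.05, and the rotation test fry called 3 higher (interferon, mesenchymal side, Wnt antagonists) and 6 lower (epithelial side, basal, suprabasal, wound, cholesterol, Frizzled receptors). Camera with the preset correlation also shifted 10 to 26 lists in each of the 9 other splits of the 6 arrays into 3 and 3. Those splits mix the genotypes, so part of the genotype difference remains in them. Of the 22 shifted lists, 12 stayed shifted without any 1 array. The Sfrp, Wnt ligand, Wnt antagonist, pluripotency, hair follicle, cytokine and DNA repair lists had median levels under 4.82, the lowest background level, in both genotypes. Those of the Wnt/beta-catenin target, Hedgehog, Notch, NF-kB, sebaceous gland and ABC transporter lists were no higher than 5.10, the highest background level. Medians near 0 in these lists do not show that the genes were unchanged.

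Markers of other cell types that a gate on skin tumour tissue could hold showed few differences besides the leukocyte and fibroblast lists above. The median level of each of these other lists lay between 4.10 and 4.49 in both genotypes, under the lowest background level of 4.82. List medians near 0 there do not show that such cells were absent or unchanged. The neutrophil list was lower in Sfrp1_KO (median -0.21, or -0.90 with dim features left out; camera adjusted p = 0.0175; adjusted p = 0.679 with an estimated correlation, and 0.118 by camera without Sfrp1_KO replicate 2), and none of its 13 genes passed in either adjustment. S100a9, which keratinocytes also make, was at 6.71 ± 0.35 and 5.17 ± 0.72 (SD, n = 3), and S100a8 passed without WT replicate 1 (-1.05, limma adjusted p = 0.0268). Thy1, shared with fibroblasts, was the 1 of 14 T and NK cell markers that rose in either adjustment (median -0.01, mean 0.05, camera pointing up with adjusted p = 0.767). None of 16 endothelial, 12 Langerhans and dendritic, 10 mast cell, 9 melanocyte, 14 skeletal muscle, 5 erythroid and 8 adipocyte markers passed in either adjustment. The list medians were -0.11, -0.03, -0.04, -0.04, -0.02, -0.04 and 0.01 (adjusted p = 0.628, 0.781, 0.437, 0.882, 0.781, 0.584 and 0.628), the means of the endothelial, melanocyte and adipocyte lists having the opposite sign (0.04, 0.02 and -0.15). The endothelial genes Flt1 and Cdh5 passed without Sfrp1_KO replicate 3 (0.86, adjusted p = 0.0379, and 2.34, adjusted p = 0.0337), and Flt1 with array weights (0.73, adjusted p = 0.0478). Xist, the RNA of the inactive X chromosome, was at 13.50, 13.49 and 6.73 on WT replicates 1, 2 and 3 and between 12.90 and 13.71 on the Sfrp1_KO arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty lay under background on all 6 arrays.

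No shift of a whole chromosome was called. With 3 arrays per genotype and most genes under background, this does not exclude such shifts. None of 21 chromosomes shifted between the genotypes by camera (lowest adjusted p = 0.766, chromosome 15; 1 with an unadjusted p under 0.05), and none did with an estimated correlation or by fry. Around Sfrp1 on chromosome 8, 6 of 228 genes within 10 Mb were called (2.63%) against 33 of 1137 on the rest of the chromosome (2.90%; Fisher's exact test, two-sided p = 1), and 8 of 404 within 20 Mb (1.98%) against 31 of 961 (3.23%; p = 0.285).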

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

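The features that the gene comparison leaves out also held signal that differed between the genotypes. In a fit over all 65956 transcript clusters, 96 features with no listed gene symbol were higher and 34 lower in Sfrp1_KO, and of features with several symbols 21 were higher and 14 lower. Among the features with no listed symbol, 4 are named here, chosen after their values were seen. Higher were TC0800003101.mm.1 (8.77 ± 1.28 in WT and 19.42 ± 0.0092 in Sfrp1_KO, SD, n = 3; limma adjusted p = 0.00138) and TC0200003789.mm.1 (11.66 ± 0.24 and 18.59 ± 1.59; adjusted p = 0.0118). Lower were TC1400001972.mm.1 (19.88 ± 0.05 and 6.13 ± 0.24; adjusted p = 4.11e-07) and TC1200000942.mm.1 (8.76 ± 1.32 in WT, and 3.92 ± 0.82 in Sfrp1_KO, under background on all 3 arrays, so lower by at least 3.69; adjusted p = 0.0322). The highest values of the first 3 lay within 0.50, 0.35 and 0.0036 of the highest value on their array, near the upper end of the scale, where differences can be compressed, so the 4 are not ranked by size. The gene behind each is not given in the sources used here, and no explanation of these differences was tested.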

How the results depend on the processing

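With 3 arrays per genotype the calls depended on which arrays were used. No called gene changed sign under another fit or without any 1 array. Every called gene separated the arrays of the genotypes, so leaving out or weighting arrays, or the block, could not have changed a sign. Leaving out 1 array gave 191 to 487 genes higher and 100 to 407 lower, of which 154 and 91 were called in all 6 cases, and it left 7 to 12 lists higher. In the same cases Cd34 ran from 1.29 to 1.97, Itga6 from -2.14 to -1.53, Epcam from -3.03 to -2.01 and Ptprc from -0.022 to 0.11. The replicate number as a block called 297 genes higher and 238 lower and ended the calls of 39 genes named in the report (adjusted p from 0.0503 to 0.139), each given there, with Itga6 (-1.89, adjusted p = 0.0608) and Epcam (-2.56, adjusted p = 0.0981) among them. The block leaves their differences as they are. It also ended the call of the TGF-beta list (0.0528) and shifted the unfolded protein response list (0.0399). Deviations of same-numbered arrays correlated across genes with r of 0.180, -0.122 and 0.171, and those of differently numbered arrays with r of -0.33 to 0.25. With 3 arrays per genotype these values do not decide whether the numbers pair the samples, and the labels do not say. The test without moderation called 14 and 21 with fewer degrees of freedom, and a minimum of 1 log2 unit left 295 and 244. Cd34 passed after quantile normalization once more (1.53, limma adjusted p = 0.0314) and with array weights (1.70, adjusted p = 0.0299), against 0.0558 to 0.103 in the other fits with all arrays, and the cause was not tested. An estimated correlation left 0 lists higher and 0 lower, and fry called 3 higher and 6 lower. Signal over background limits each difference given as "at least". With dim features left out, lists under 5 members and genes that were removed have no value.

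The reversals below concern results that were not called, and the cause was not tested. With dim features left out the medians were -0.035 (stem cell markers), -0.087 (endothelial) and -0.00809 (skeletal muscle). The melanocyte list stood at -0.031 after quantile normalization, -0.0537 with array weights and -0.036 by fry and by ranks. With array weights Sfrp4 was at -0.012, DNA repair at 0.0061, ribosomal proteins at 0.013 and T and NK cells at -0.040. Leaving out 1 array, single genes ran from -0.016 to 0.12 (Cpa3), -0.0049 to 0.068 (Eif2s3y), -0.071 to 0.0047 (Epor), -0.043 to 0.072 (Frzb), -0.0078 to 0.71 (H2bc1), -0.11 to 0.00073 (Kdm5d), -0.13 to 0.15 (Sfrp4), -0.13 to 0.11 (Sfrp5) and -0.30 to 3.09 (Xist). List medians ran from -0.044 to 0.015 (DNA repair), -0.019 to 0.077 (G1/S), -0.031 to 0.099 (NF-kB), -0.17 to -0.0051 (NRF2), -0.10 to 0.011 (cytokines), -0.14 to 0.025 (ribosomal proteins) and -0.65 to -0.0084 (hypoxia). They ran from -0.14 to -0.038 (mTORC1), -0.079 to 0.039 (Langerhans), -0.048 to 0.022 (T and NK cells), -0.17 to 0.031 (endothelial), -0.074 to -0.010 (melanocyte), -0.047 to 0.0015 (muscle), -0.044 to 0.016 (metalloproteinases) and -0.061 to 0.0035 (stem cell markers). Where a range keeps 1 sign, the direction of the list test turned and not the median. The neighbourhood of Sfrp1 ran from -0.039 to 0.018 within 10 Mb and from -0.030 to 0.016 within 20 Mb.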

Other observations

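The tests of collagens, of 4 abundant pericyte and smooth muscle transcripts, leukocyte markers, background probe sets and Y-linked genes were chosen after the results they address were seen, as were the added marker lists and the requirement that the tests of background probe sets and of X-linked escape genes hold over a bootstrap spread, and the rules that leave a test undecided near background or after normalization. Bounds on the list medians of pericytes and smooth muscle cells and of dermal papilla cells had been set beforehand. They were met, but 6 of the 10 genes of each list lay under background on every array, so neither decides. Bootstrap spreads, bounds and intervals here resample the genes of a list and not the arrays. They do not measure the spread between samples, and genes of a list are not independent.

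Added lists covered further cell types of the skin. None of 10 pericyte and smooth muscle genes was called, and their median log2 difference was -0.088. Of 6 measured Schwann cell genes Erbb3, a receptor kinase that epithelial cells also express, fell by 1.32 (SE 0.12), none rose, and the median was 0.013. Of 10 dermal papilla genes Vcan, which encodes the matrix proteoglycan versican, rose by 1.84 (SE 0.20) and the growth factor gene Fgf7 by at least 0.065, with a list median of 0.063.

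In Sfrp1_KO 12 of 29 genes of the epithelial side of the transition were lower and 8 of 27 of the mesenchymal side higher, with 1 lower (adjusted p = 0.138 and 0.386 for the lists with an estimated correlation). Epcam RNA itself was at 5.03 ± 0.17 (SD, n = 3) in Sfrp1_KO, around background, although the cells were sorted as positive for Epcam. The sorted fractions of the genotypes may therefore not hold the same cells. Other cells that passed the lineage gate and the selection for Epcam are a candidate explanation. Fibroblasts rich in collagen would raise Col1a1, Col1a2 and Col3a1 about as far as Vim, but the highest upper 95% bound of their differences was 1.54 and their means in Sfrp1_KO stayed at 6.82 or below, which argues against them. For pericytes or smooth muscle cells the upper bootstrap bound of the list median was 0.018 and for dermal papilla cells 0.42, both under the 1 log2 unit set beforehand, but most genes of both lists lay under background, which can hold a median near 0. Pdgfrb, which pericytes and fibroblasts share, rose by 3.72 and Vcan and Fgf7 of the dermal papilla list rose too. The highest upper 95% bound of Acta2, Tagln, Myh11 and Rgs5 was 0.85, with Acta2 at 7.05 ± 1.13 in WT and 6.43 ± 0.73 in Sfrp1_KO (SD, n = 3) and the others around or under background. Mcam of the pericyte and smooth muscle list was at 7.15 ± 0.61 and 5.70 ± 0.03 and not called (limma adjusted p = 0.0552). These values go both ways and most genes lie near background, so both cell types stay open. Other stromal cells low in collagen and a mesenchymal state of the tumour cells linked to the genotype stay open too and were not tested.

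Of 31 interferon-response genes 21 were higher in Sfrp1_KO (adjusted p = 0.229 for the list with an estimated correlation). Leukocytes and more signal overall were considered as sources. The interferon median exceeded that of the leukocyte and macrophage markers by 0.60 (95% bootstrap interval 0.32 to 1.14), but in WT the medians of both lists, 4.89 and 4.48, lay under the mean background level, where differences are compressed, so this comparison decides nothing. Leukocytes that passed the lineage gate stay open as a source. The largest absolute difference of a background probe set was 0.40, but RMA had already brought the array medians to between 4.32 and 4.46 and these sets lie at the floor, so it decides nothing. After RMA the median difference of all genes was -0.01, with 552 genes higher and 437 lower. Genes above background made up 33.2% to 35.0% on Sfrp1_KO arrays and 34.5% to 42.5% on WT arrays. These values, chosen after the results were seen, show no rise over all genes in the normalized values, beside an interferon median of 0.91. The 95% bootstrap interval of that median, over genes and not arrays, was 0.69 to 1.35. RMA brings the array medians together, and the share above background rests on the highest background probe set of each array. More signal before RMA therefore stays open as a source. A response of the tumour cells linked to the genotype was not tested.

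Xist in WT replicate 3 differed by -6.76 log2 units from the mean of WT replicates 1 and 2, and a male mouse or the loss of the inactive X chromosome may explain it. The largest difference of 3 Y-linked genes in the same comparison was 0.048, which argues against a male mouse with its Y chromosome, although no array here shows how those probe sets respond and a tumour that lost the Y stays open. The median difference of 7 genes that escape X inactivation was -0.079, at percentile 34.4 of 10000 random lists of like expression. Its bootstrap spread covers percentiles 0.46 to 81.5 and 3 of the 7 lie near background, so loss of the inactive X stays open. The counts without this array stand with the gene counts of the report.

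The 6 arrays can be split in 10 ways, too few for a share under 0.05. The splits other than by genotype put arrays of both genotypes on both sides, so the genotype difference widens the spread within their groups. Few called genes in them were therefore likely from the start and do not exclude chance. The split by genotype called 989 genes, and the highest of the other splits called 0. It shifted 22 lists by camera with the preset correlation, while each of the 9 other splits shifted between 10 and 26, the highest being WT replicate 1 with Sfrp1_KO replicates 1 and 2. No chromosome shifted by genotype (0), and the highest other split shifted 1. As many results as by genotype came from 1, 2 and 10 of the 10 splits, the real one included.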
